A study of Mus musculus with 18 samples.

How the data were processed

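QuantSeq 3′ mRNA sequencing was run on RNA, isolated with Qiagen RNeasy per the labels, from AT3 mouse mammary carcinoma cells treated with DMSO, 20 µM STM2457 or 2 µM STM3006 for 24 h or 48 h. There were 6 groups of 3 libraries, 18 in all, with 3781443 to 6647274 counts each. The deposited table holds raw counts per gene, with no normalization, for 15120 genes, each with a total of at least 10 counts over the 18 libraries. The processing notes of the authors name bcl2fastq, HISAT2, HTSeq, DESeq2 and the mm10 build, without versions or settings. Neither the annotation release nor the strand setting of the counting is given. Counts of genes with nearly identical copies (Dcpp1, Dcpp2 and Dcpp3, H2-K1 and H2-D1, the Ifit family, histone genes) may therefore hold reads of a relative. No symbol was given for 43 genes, and 6 shared a symbol with another.

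Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 11143 and set aside 3977, the remaining genes holding 99.8% of the counts. Library sizes were scaled by TMM. One quasi-likelihood model with a coefficient per group was fitted to all 18 libraries with robust shrinkage, so that all groups shared 1 estimate of the spread (common biological coefficient of variation 13.9%). Each comparison was a contrast of this model, tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p below 0.05. There were 9 comparisons, namely each compound against DMSO at each time, STM3006 against STM2457 at each time, DMSO at 48 h against 24 h, and the difference of each compound's effect between 48 h and 24 h. The labels do not say what libraries of the same number share, so the number was not used as a block. CPM are edgeR's, on TMM-scaled library sizes, fold changes used edgeR's prior count of 0.125, and log2 CPM for the principal components a prior count of 2. Standard errors on the log2 scale come from the model.

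There were 29 gene lists: interferon-stimulated genes, nucleic acid sensing, interferons with their receptors and JAK-SOCS signalling, MHC class I and antigen processing, chemokines and cytokines, immune checkpoint ligands, NF-kB targets, m6A writer complex, m6A readers and erasers, DNA replication and G1/S, G2/M and mitosis, p53 targets, integrated stress response, unfolded protein response, apoptosis regulators, MYC and ribosome biogenesis, cholesterol synthesis and uptake, hypoxia and glycolysis, mesenchymal and matrix genes, epithelial genes, immediate early genes, lysosome and autophagy, leukocyte, fibroblast, endothelial and adipocyte markers, cytosolic ribosomal proteins, mitochondrial-encoded transcripts, and Zfp-numbered zinc finger genes. Few genes stand in more than 1 list: Vegfa (chemokines, hypoxia), Sesn2 (p53, integrated stress response), Atf3 (integrated stress response, immediate early), Zfp36 (immediate early, zinc finger), and Bax, Bbc3, Pmaip1, Fas and Tnfrsf10b (p53, apoptosis). For each list the members called were counted over all genes and with p-values adjusted over the list alone. Limma's camera with a preset correlation of 0.01 was the test of a list, with camera on an estimated correlation and limma's fry beside it, and Benjamini-Hochberg adjustment over the 29 lists within a comparison. Fry tests whether a list's genes move one way on balance and does not compare them with other genes.

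Named genes followed a rule: the 8 highest and 8 lowest log2 changes among called genes with a mean of at least 5 CPM and no overlap between the groups, with predicted genes, mitochondrial genes and pseudogenes passed over, up to 4 called members of each list with the smallest adjusted p, the 4 highest and 4 lowest for the time comparisons, and always a set of genes, among them Mettl3, Mettl14, Ifnb1, Ifit1, Isg15, Irf7, Cxcl10, Cd274, H2-K1, B2m and Tap1. The text names part of these, mostly those that kept their call under every alternative, and 4 genes that the rule gave are not reported here. Isg15 and Oasl1 in the difference of the STM3006 effects, and Cxcl5 there, were chosen after their values were seen. Comparisons, lists, this rule and most alternatives were fixed before the data were examined.

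Alternatives were size factors of DESeq2's kind, no filter on low counts, a filter at a mean of 5 CPM, DESeq2 1.42.0, only the libraries compared, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were corrections of each library for a smooth trend on the GC content of the last 500 bases of the longest transcript or on its length, and the lists without the STM3006 48 h library numbered 2. Coordinates, lengths and exons come from GENCODE release 21 for mouse, in which 15030 gene identifiers (99.4%) were found. Precision was tested on simulated data with 50 genes changed per fold: of those changed 1.5-fold, 2-fold, 4-fold and 8-fold, 22%, 78%, 100% and 98% were called for STM2457 against DMSO at 48 h, and 12%, 42%, 96% and 98% for the difference of the STM3006 effects, with 4.49% and 6.77% of the calls false. The changed genes were drawn from those with a mean of at least 5 CPM, so the shares called do not cover lower ones. The simulated groups all had the same spread. These shares therefore do not cover the wider spread of the measured STM3006 48 h libraries. Genes set aside by the filter, among them Mettl3 and Cxcl10, were given as counts only.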

Results

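Messenger RNA was measured in AT3 cells, a mouse mammary carcinoma line derived from an MMTV-PyMT tumour, after treatment with an inhibitor of METTL3, the enzyme that places N6-methyladenosine (m6A) on messenger RNA. The compounds, known by the code names STM2457 and STM3006, were given at 20 µM and 2 µM, and DMSO was the vehicle. Cells were collected after 24 h and 48 h, which makes 6 groups of 3 libraries and 18 libraries in all. Each library was made by QuantSeq 3′ mRNA sequencing, which reads the 3′ end of polyadenylated transcripts. The total per library was 3781443 to 4629117 counts, except for the library numbered 2 of STM3006 at 48 h, which held 6647274. The table held 15120 genes, and 11143 of them, with 99.8% of the counts, had enough counts to be tested. Depth set a floor of 3 counts, which is 0.451 to 0.793 CPM (counts scaled by the library total) depending on the library, and such floors cover counting error only. The labels do not say whether the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these samples.

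Expression is given below as normalised CPM, mean ± SD, and changes as log2 fold change ± SE, with n = 3 per group. A gene was called at an adjusted p below 0.05 in the edgeR quasi-likelihood test. For each gene named among the highest or lowest of a comparison of treatments, all 3 libraries of one group lay beyond all 3 of the other, which chance alone gives for 10% of genes. Coordinates are on mm10. The first 3 principal components held 28.7%, 24.7% and 9.38% of the variance. The 3 libraries of STM3006 at 48 h spread more widely around their group mean than those of any other group, with residual SDs of 0.298, 0.387 and 0.329 on the log2 scale. Residual SDs of the other libraries ran from 0.194 to 0.287.

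Mettl3 itself had 0 to 5 counts per library and 43 counts in all, too few to test, and the compounds inhibit the protein rather than remove the transcript. Mettl14, the partner of METTL3 in the methyltransferase, was not called in any comparison with DMSO, with log2 changes of -0.03 (STM2457) and -0.08 (STM3006) at 24 h and 0.17 and -0.19 at 48 h. Cxcl10 had 1 to 16 counts per library and was not tested. Ifnb1 and Cd274 were not analysed here.

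STM2457 was compared with DMSO at 24 h to ask which transcripts the METTL3 inhibitor changed first, among them those of the interferon response named in the study's title. Ifit1bl1, a member of the interferon-induced Ifit family (ENSMUSG00000079339, chromosome 19, 34592891 to 34601956), rose 6.03-fold, from 4.39 ± 0.549 CPM to 26.6 ± 1.02 (SD, n = 3), a log2 change of 2.59 ± 0.37 with adjusted p = 1.4e-04. Metrnl, which encodes the secreted meteorin-like protein (ENSMUSG00000039208, chromosome 11, 121701544 to 121716306), rose 4.37-fold from 10.9 ± 0.971 to 47.7 ± 2.87 CPM (SE 0.15 on the log2 scale). Slc25a48, a mitochondrial carrier gene (ENSMUSG00000021509, chromosome 13, 56438355 to 56474239), rose from 10.8 ± 2.18 to 43.2 ± 4.34 CPM. Brf2, a subunit of an RNA polymerase III initiation factor, rose 3.71-fold, and the protease inhibitor genes Wfdc17 and Spink12 rose 3.39-fold and 3.16-fold. On the other side, Dcpp3 and Dcpp1, which encode secreted salivary-type proteins, fell by 4.21 ± 0.71 and 3.11 ± 0.58 on the log2 scale. The Dcpp copies are nearly identical, so reads may not be assigned to the right one. Cyp26b1, which breaks down retinoic acid, fell from 101 ± 14.2 to 25.1 ± 1.22 CPM, and the histone gene Hist3h2a from 231 ± 13.3 to 60.0 ± 3.07. Rbmx, an RNA-binding protein gene (ENSMUSG00000031134, chromosome X, 57383530 to 57393036), fell from 56.7 ± 4.45 to 14.9 ± 3.53 (log2 change -1.92 ± 0.25). In total 1302 genes were called, 858 higher and 444 lower, and 268 of them changed at least 2-fold.

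Of the 58 interferon-stimulated genes tested at 24 h of STM2457, 18 rose and 1 fell over all genes, and 23 rose and 1 fell adjusted over the list alone, with a median log2 change of 0.35 and 47 members above 0. As a list they were called higher (camera adjusted p = 3.4e-06, adjusted p = 0.145 with an estimated correlation). Rtp4 (ENSMUSG00000033355, chromosome 16, 23520291 to 23614222) rose 2.68-fold from 138 ± 14.6 to 369 ± 5.36 CPM. The antiviral gene Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) rose 2.39-fold from 40.7 ± 3.33 to 97.2 ± 16.2 CPM (adjusted p = 0.0013). The ubiquitin-like modifier gene Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818) rose 1.94-fold from 253 ± 18.1 to 491 ± 83.7. The interferon-inducible GTPase genes Ifi47 and Iigp1 rose 2.72-fold and 2.42-fold, while Ifi27 fell by 0.84 ± 0.11. Irf7 (0.10 ± 0.17, adjusted p = 0.76), a transcription factor of this response, was not called. In nucleic acid sensing, 3 of 19 genes were called higher and 6 adjusted over the list alone (camera adjusted p = 0.0784). Tlr3, the endosomal receptor for double-stranded RNA, rose by 0.60 ± 0.12. NF-kB targets had 5 of 17 higher and 1 lower, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.145 with an estimated correlation). Nfkbie, Ier3 and Rela were higher by 1.47, 0.69 and 0.53 and Lcn2 lower (-0.65). In MHC class I and antigen processing 1 of 22 genes was higher (camera adjusted p = 0.532). H2-K1 (0.30, adjusted p = 0.12), B2m (0.06) and Tap1 (0.10) were not called.

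In the m6A writer complex 3 of 8 genes were higher at 24 h of STM2457 over all genes and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0887). Among them, Cbll1 rose from 13.2 ± 0.784 to 23.1 ± 1.99 CPM. Among readers and erasers, also not called as a list, 3 of 12 were higher and 1, Rbmx, lower (camera adjusted p = 0.46). Ythdf2, whose protein binds m6A and promotes decay (ENSMUSG00000040025, chromosome 4, 132184912 to 132212303), rose 2.03-fold from 138 ± 16.5 to 280 ± 14.4 CPM (adjusted p = 2.8e-06), and its nuclear relative Ythdc1 rose 1.75-fold.

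The integrated stress response had 5 of 24 lower and 1 higher at 24 h of STM2457, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.0337 with an estimated correlation). The lipoprotein receptor gene Vldlr, the transcription factor gene Atf5 and the mTOR inhibitor gene Ddit4 had log2 changes of -1.25 ± 0.19, -0.95 ± 0.15 and -0.77 ± 0.16. Of the hypoxia and glycolysis genes 4 of 27 fell (camera adjusted p = 0.00494, adjusted p = 0.145 with an estimated correlation). They included Egln3, an oxygen-sensing prolyl hydroxylase (-1.04 ± 0.23), and Ndrg1 (-0.62 ± 0.13). In DNA replication and G1/S 3 of 30 were lower, Pola1 among them at -0.63 (camera adjusted p = 0.0141, adjusted p = 0.499 with an estimated correlation). In G2/M and mitosis 2 of 30 were lower (camera adjusted p = 0.0016, adjusted p = 0.0536 with an estimated correlation). Of 23 cholesterol genes 5 were higher and 6 adjusted over the list alone (camera adjusted p = 0.0502). Epithelial genes had 3 of 22 higher and 5 lower (camera adjusted p = 0.345). The keratin genes Krt5 and Krt14 had log2 changes of -1.01 and -0.68. Lysosome and autophagy had 5 of 28 higher (0.345). The lysosomal enzyme gene Neu1 had a log2 change of 0.72. MYC and ribosome biogenesis had 3 of 28 higher (0.345). The rRNA methyltransferase gene Nop2 had a log2 change of 0.90 ± 0.10. Immediate early genes had 5 of 27 higher and 1 lower (0.222).

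No other list was called by camera at 24 h of STM2457. Members higher and lower were 2 and 1 of 13 for interferons, their receptors and JAK-SOCS signalling, 2 and 0 of 15 chemokines and cytokines, and 1 and 0 of 9 immune checkpoint ligands. They were 1 and 2 of 25 p53 targets, 0 and 0 of 17 for the unfolded protein response, 1 and 2 of 22 apoptosis regulators, and 1 and 3 of 28 mesenchymal and matrix genes. Among markers of other cell types they were 0 and 0 of 2 leukocyte, 0 and 1 of 7 fibroblast, 0 and 0 of 4 endothelial and 1 and 0 of 2 adipocyte genes. They were 0 and 1 of 78 cytosolic ribosomal proteins, 0 and 0 of 21 mitochondrial-encoded transcripts, and 11 and 3 of 227 Zfp-numbered zinc finger genes. Camera adjusted p-values of these lists ran from 0.293 to 0.807. Median, mean and test differed in sign for m6A readers and erasers, the unfolded protein response, MYC and ribosome biogenesis, and mesenchymal and matrix genes. The count of called genes moved by more than 1.5 times without DMSO library 1 (832), 2 (763) or 3 (783) or STM2457 library 1 (730). The number of interferon-stimulated genes called higher was 11 without DMSO library 1. With only the 6 libraries compared in the fit 2129 genes were called.

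**Figure D1:**
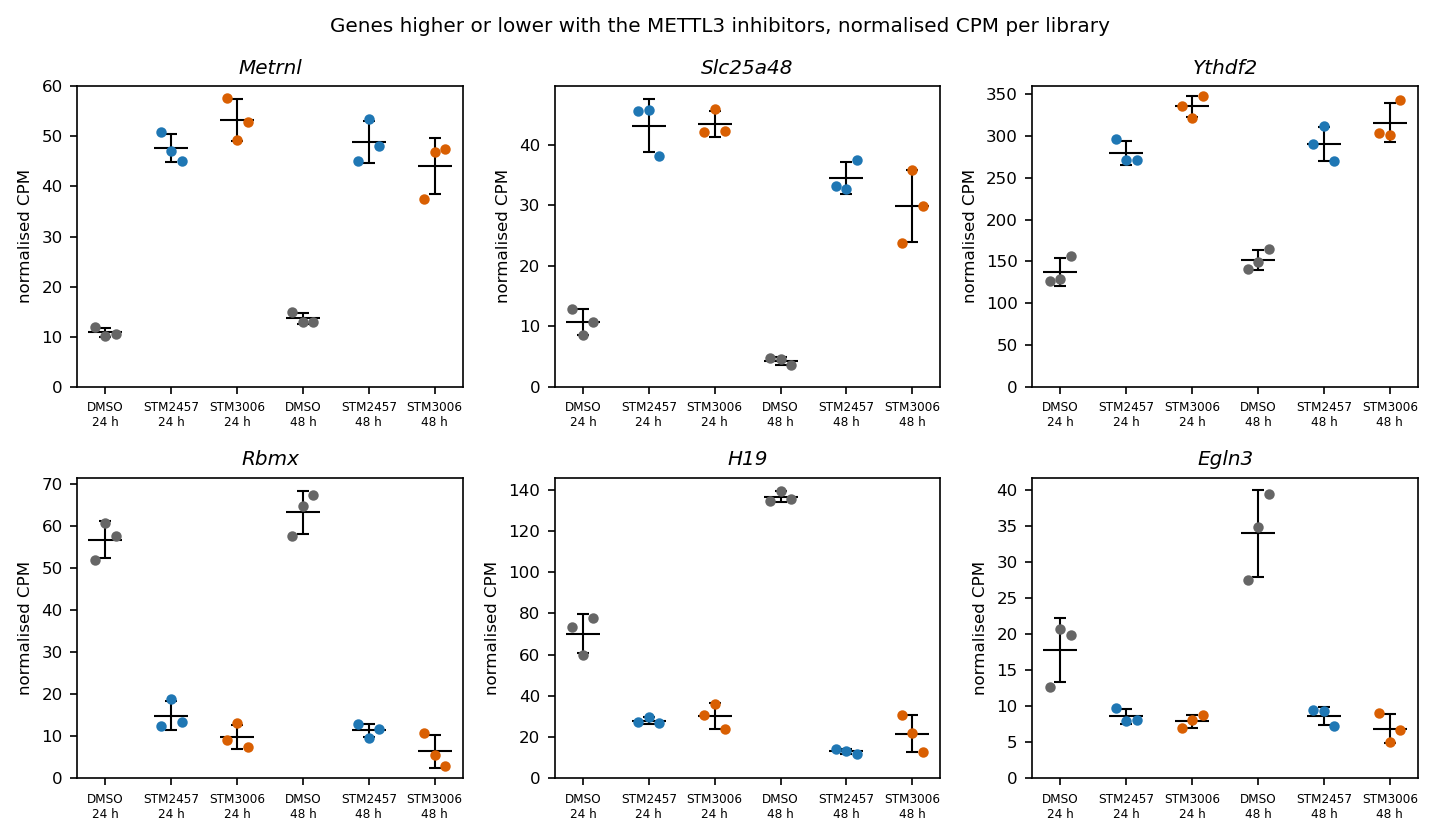
Normalised CPM (y axis, from 0) of 6 genes in each of the 18 libraries (points) by treatment and time, with the group mean and SD as bars. Metrnl was 10.9 ± 0.971 CPM with DMSO and 47.7 ± 2.87 with STM2457 at 24 h, and H19 136 ± 2.70 with DMSO and 13 ± 1.23 with STM2457 at 48 h.

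STM3006 at 24 h posed the same question for the other compound, at a dose of 2 µM instead of 20 µM, so the doses differ. Ifit1bl1 rose 9.75-fold to 43.0 ± 2.84 CPM (log2 change 3.28 ± 0.36, adjusted p = 5.3e-06), Metrnl 4.88-fold to 53.2 ± 4.25 and the tight junction gene Cldn4 5.84-fold to 13.7 ± 3.02. Pomgnt2, an enzyme of protein O-mannosylation in the endoplasmic reticulum, rose 4.33-fold from 9.03 ± 0.568 to 39.2 ± 1.02 CPM (adjusted p = 7.6e-08). Dcpp1 fell by 4.64 ± 0.68 on the log2 scale, and Hist3h2a and the linker histone gene Hist1h1c were 7.98-fold and 4.78-fold lower. Rbmx was 5.77-fold lower at 9.85 ± 2.88 CPM, and Cdh15, a cadherin gene, 5.72-fold lower at 4.70 ± 0.505. In total 2367 genes were called, 1370 higher and 997 lower, and 516 changed at least 2-fold.

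Of the 58 interferon-stimulated genes 16 rose and 3 fell at 24 h of STM3006, and 18 and 3 adjusted over the list alone, with a median log2 change of 0.38 and 44 members above 0. Camera called the list (camera adjusted p = 0.00131, adjusted p = 0.336 with an estimated correlation). Rtp4 rose 3.18-fold to 438 ± 39.5 CPM, and Ifi47 3.27-fold. Ifit1 rose 2.42-fold to 98.3 ± 17.1 (adjusted p = 6.2e-04) and Isg15 2.11-fold to 534 ± 36.1 (adjusted p = 2.8e-04), while Ifi27 fell by 1.08 ± 0.11. Irf7 was not called (-0.04, adjusted p = 0.89). Nucleic acid sensing had 7 of 19 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.149). Tlr3 rose by 0.86 ± 0.12 and Tmem173, the adaptor STING, by 0.84 ± 0.16. NF-kB targets had 8 of 17 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0315, adjusted p = 0.208 with an estimated correlation). Nfkbie, Rela and Ier3 had log2 changes of 1.5, 0.62 and 0.61. The lists of interferons, receptors and JAK-SOCS signalling had 5 of 13 higher and 1 lower (camera adjusted p = 0.163). Chemokines and cytokines had 4 of 15 higher (0.0701) and immune checkpoint ligands 2 of 9 higher (0.0963). The interferon gamma receptor gene Ifngr2 had a log2 change of 1.04, Cxcl16 of 0.63 and Cd276 of 0.79. In MHC class I and antigen processing 1 of 22 was higher (0.864), and H2-K1 (0.12), B2m (0.10) and Tap1 (-0.12) were not called.

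Ythdf2 rose 2.44-fold to 335 ± 13.1 CPM at 24 h of STM3006, Ythdc1 2.01-fold to 108 ± 1.91, and Ythdf1 by 0.66 on the log2 scale. Of 12 readers and erasers 3 were higher and 1 lower (camera adjusted p = 0.359). In the writer complex 2 of 8 were higher (0.143), Cbll1 among them at 0.88. DNA replication and G1/S had 10 of 30 lower and 13 adjusted over the list alone (camera adjusted p = 0.00131, adjusted p = 0.279 with an estimated correlation). Pola1 and Clspn had log2 changes of -0.78 and -0.73. G2/M and mitosis had 8 of 30 lower (camera adjusted p = 0.00132, adjusted p = 0.0522 with an estimated correlation). Cdca8 and Nusap1 had log2 changes of -0.75 and -0.67. The integrated stress response had 7 of 24 lower and 1 higher, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.0421 with an estimated correlation), with Atf5 at -1.0 and the folate enzyme gene Mthfd2 at -0.52. Hypoxia and glycolysis had 9 of 27 lower (camera adjusted p = 0.00408, adjusted p = 0.208 with an estimated correlation). Egln3, Aldoc and Ndrg1 had log2 changes of -1.15, -0.89 and -0.83. Cholesterol genes had 2 of 23 higher and 5 lower (camera adjusted p = 0.242), with lanosterol synthase, Lss, at -0.68 ± 0.16 and Hmgcs1 at -0.44 ± 0.11. Gdf15, a stress-induced cytokine among the p53 targets, rose 3.15-fold from 20.5 ± 8.75 to 65.0 ± 4.25 CPM. Of the 25 targets 4 were higher and 1 lower (0.846).

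The cytosolic ribosomal proteins had 4 of 78 lower and none adjusted over the list alone at 24 h of STM3006 (camera adjusted p = 0.0424, adjusted p = 0.646 with an estimated correlation). The Zfp-numbered zinc finger genes had 41 of 227 higher and 6 lower (camera adjusted p = 0.0493, adjusted p = 0.208 with an estimated correlation). Members higher and lower were 4 and 4 of 22 epithelial genes, with the desmosome gene Dsp at -1.07, 3 and 4 of 28 mesenchymal and matrix genes, and 5 and 3 of 27 immediate early genes. They were 5 and 2 of 28 for MYC and ribosome biogenesis, 3 and 1 of 28 for lysosome and autophagy, 1 and 1 of 17 for the unfolded protein response, 2 and 1 of 22 apoptosis regulators, and 0 and 3 of 21 mitochondrial-encoded transcripts. Among markers of other cell types, 1 leukocyte and 1 endothelial gene were higher. Camera adjusted p-values of these lists ran from 0.153 to 0.994. Median, mean and test differed in sign for p53 targets, the unfolded protein response, apoptosis regulators, MYC and ribosome biogenesis, epithelial genes, lysosome and autophagy, and fibroblast markers. The count of called genes was 1483 without DMSO library 2, 1576 without DMSO library 3, and 3603 with only the 6 libraries compared in the fit.

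At 48 h STM2457 was compared with the DMSO cultures of that time, to ask what the longer exposure changed. Il1rn, the antagonist of the interleukin 1 receptor (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494), rose 9.84-fold from 1.43 ± 0.227 to 14.4 ± 5.05 CPM (log2 change 3.30 ± 0.30, adjusted p = 1.5e-07). Wfdc17 rose 9.10-fold to 29.6 ± 2.04 CPM, Ifit1bl1 8.26-fold to 21.3 ± 4.88 and Slc25a48 7.95-fold to 34.5 ± 2.65. The growth factor gene Bmp2 rose 6.56-fold from 4.50 ± 0.774 to 29.6 ± 4.56. Cxcl5, a chemokine for neutrophils (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), rose 2.65-fold from 21.6 ± 2.58 to 57.2 ± 2.02 CPM. H19, an imprinted long non-coding RNA (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), was 10.5-fold lower, 13 ± 1.23 against 136 ± 2.70 CPM (log2 change -3.39 ± 0.22, adjusted p = 3e-09). Dcpp1 fell by 6.48 ± 0.65 on the log2 scale, Aqp5, a water channel gene of secretory epithelia, by 2.87 ± 0.30, and Csn1s1, a casein of milk, by 2.52 ± 0.33. In total 2188 genes were called, 1127 higher and 1061 lower, and 498 changed at least 2-fold.

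Of the 58 interferon-stimulated genes 21 rose and 2 fell at 48 h of STM2457, and 26 and 2 adjusted over the list alone, with a median log2 change of 0.59 and 44 members above 0. As a list they were called higher (camera adjusted p = 3e-07, adjusted p = 0.0937 with an estimated correlation). Oasl1 (ENSMUSG00000041827, chromosome 5, 114923240 to 114937915) rose 3.21-fold from 6.17 ± 0.498 to 19.9 ± 2.69 CPM, and Ifit1 2.65-fold from 22.5 ± 6.92 to 59.5 ± 3.78 (adjusted p = 5e-04). Rtp4 rose 2.55-fold from 88.5 ± 17.2 to 226 ± 7.58 and Iigp1 2.26-fold from 26.1 ± 3.24 to 59.1 ± 2.99. Isg15 was not called (0.31 ± 0.18, adjusted p = 0.24), nor was Irf7 (0.39, adjusted p = 0.15). Nucleic acid sensing had 5 of 19 higher, and 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.0259 with an estimated correlation). Tlr3 (ENSMUSG00000031639, chromosome 8, 45395665 to 45411080) rose 2.17-fold from 86.8 ± 1.77 to 188 ± 9.68 CPM, Tmem173 1.70-fold, and Irf3, a transcription factor that acts downstream of both, by 0.60 on the log2 scale. NF-kB targets had 6 of 17 higher and 2 lower, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.00284, adjusted p = 0.042 with an estimated correlation). The subunit genes Relb and Rela were 2.61-fold and 2.03-fold higher and Lcn2 lower (-0.71). Chemokines and cytokines had 4 of 15 higher and 1 lower (camera adjusted p = 0.0111, adjusted p = 0.31 with an estimated correlation). Cxcl16 and the macrophage growth factor gene Csf1 had log2 changes of 0.96 and 0.91. In MHC class I and antigen processing 2 of 22 were higher and 2 lower, and none adjusted over the list alone (camera adjusted p = 0.904). H2-K1 was among them at 0.37 ± 0.12 (adjusted p = 0.039). This call ended with the replicate number as a block (adjusted p = 0.0581) and without any of 5 of the 6 libraries (adjusted p = 0.0609 to 0.145, all but DMSO library 3). B2m (-0.02) and Tap1 (0.14) were not called.

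The m6A writer complex had 4 of 8 genes higher at 48 h of STM2457, over all genes and adjusted over the list alone, and all 8 had a log2 change above 0. Camera called the complex as a list (camera adjusted p = 0.00437, adjusted p = 0.042 with an estimated correlation). Cbll1 (ENSMUSG00000020659, chromosome 12, 31484829 to 31499616) rose 2.40-fold from 12.1 ± 2.79 to 29.1 ± 2.54 CPM. On the log2 scale 1110037F02Rik, the gene now named Virma, rose by 0.76 and Wtap by 0.33. Ythdf2 rose from 151 ± 12.3 to 291 ± 20.4 CPM and Rbmx was 5.54-fold lower. Of 12 readers and erasers 3 were higher and 2 lower (camera adjusted p = 0.904). Hypoxia and glycolysis had 12 of 27 lower and 1 higher (camera adjusted p = 2.5e-05, adjusted p = 0.042 with an estimated correlation). Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860) was 3.89-fold lower at 8.69 ± 1.24 against 34.0 ± 6.01 CPM and Ankrd37, a hypoxia-induced gene, 5.36-fold lower. The integrated stress response had 9 of 24 lower and 1 higher, 13 and 2 adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.0259 with an estimated correlation). Atf5 was 2.21-fold lower (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658), Ddit4 at -1.12 and Atf3 higher at 1.18. DNA replication and G1/S had 9 of 30 lower (camera adjusted p = 0.00145, adjusted p = 0.31 with an estimated correlation). Ccne2, Uhrf1 and Pcna had log2 changes of -0.83, -0.65 and -0.49. G2/M and mitosis had 6 of 30 lower and 1 higher (camera adjusted p = 0.00906, adjusted p = 0.0733 with an estimated correlation). Cytosolic ribosomal proteins had 23 of 78 lower and 29 adjusted over the list alone (camera adjusted p = 4.2e-06, adjusted p = 0.31 with an estimated correlation). Rpl7a was 2.06-fold lower and Rpl24 had a log2 change of -0.94.

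Lysosome and autophagy genes had 9 of 28 higher and none lower at 48 h of STM2457 (camera adjusted p = 0.204). Neu1 and the cathepsin gene Ctsb had log2 changes of 0.68 and 0.44. Immediate early genes had 4 of 27 higher and 3 lower (0.548), with Fosl2 2.32-fold higher and Dusp6, a phosphatase of ERK, 3.08-fold lower. Epithelial genes had 5 of 22 higher and 4 lower (0.746), with the transcription factor gene Ovol1 at 1.90 and Krt5 at -1.28. Mesenchymal and matrix genes had 1 of 28 higher and 4 lower (0.986). Vim had a log2 change of -0.76. Members higher and lower were 4 and 2 of 25 p53 targets, 5 and 6 of 28 for MYC and ribosome biogenesis, and 3 and 3 of 23 cholesterol genes. They were 0 and 2 of 17 for the unfolded protein response, 3 and 1 of 22 apoptosis regulators, 1 and 1 of 13 for interferons, receptors and JAK-SOCS signalling, and 1 and 1 of 9 immune checkpoint ligands. They were 1 and 0 leukocyte, 2 and 1 fibroblast, 0 and 0 endothelial and 1 and 0 adipocyte markers, 0 and 1 of 21 mitochondrial-encoded transcripts, and 25 and 8 of 227 zinc finger genes. Camera adjusted p-values of these lists ran from 0.204 to 0.904. Median, mean and test differed in sign for immune checkpoint ligands, m6A readers and erasers, and cholesterol genes. Of the leukocyte markers 2 were tested, and Cd68, which encodes a lysosomal protein of macrophages and other cells, was the called one, at 1.19. The count of called genes was 1370 without DMSO library 1 and 1458 without STM2457 library 2, and 3342 with only the 6 libraries compared in the fit.

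**Figure D2:**
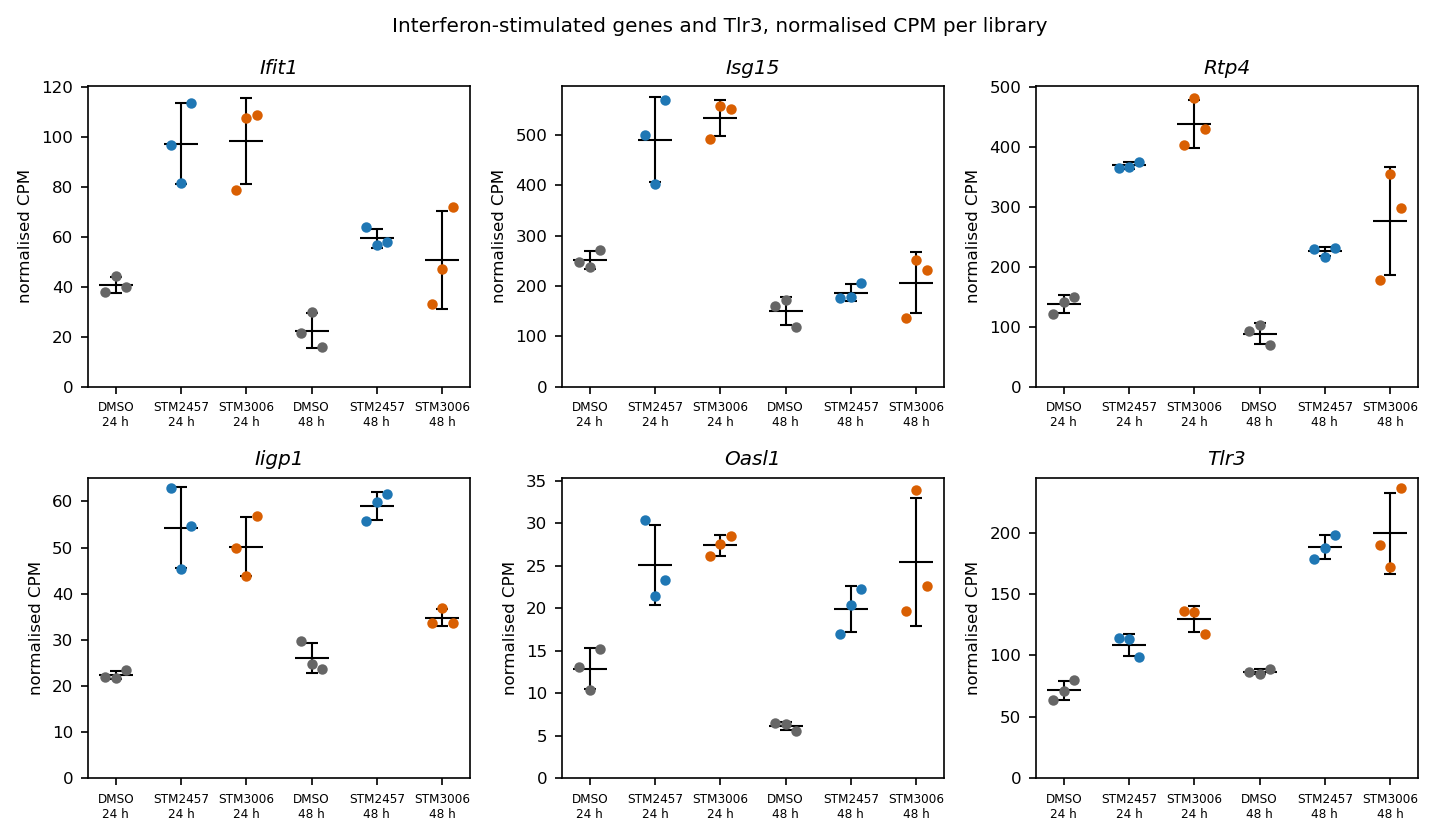
Normalised CPM (y axis, from 0) of 5 interferon-stimulated genes and Tlr3 in each of the 18 libraries (points) by treatment and time, with the group mean and SD as bars. Rtp4 was 138 ± 14.6 CPM with DMSO and 369 ± 5.36 with STM2457 at 24 h, and 88.5 ± 17.2 and 226 ± 7.58 at 48 h.

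STM3006 was compared with DMSO at 48 h, where its libraries spread most. The complement protease gene C1s1 was 8.56-fold higher at 10.4 ± 3.43 CPM. Ifit1bl1 was 8.62-fold, Osr2, a transcription factor gene, 8.16-fold, Il1rn 7.74-fold and Slc25a48 6.91-fold higher, with the last at 29.9 ± 6.0 CPM (adjusted p = 2.2e-08). Cxcl5 rose 3.05-fold to 65.9 ± 1.23 CPM. Rbmx was 9.92-fold lower, 6.37 ± 3.99 against 63.2 ± 5.02 CPM (log2 change -3.31 ± 0.27, adjusted p = 6.8e-08). Aqp5 was 12.6-fold, Csn1s1 8.54-fold and Hist3h2a 6.86-fold lower. In total 3192 genes were called, 1755 higher and 1437 lower, and 729 changed at least 2-fold.

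Of the 58 interferon-stimulated genes 16 rose and 5 fell at 48 h of STM3006, and 18 and 5 adjusted over the list alone, with a median log2 change of 0.41 and 41 members above 0. Camera called the list (camera adjusted p = 0.0221, adjusted p = 0.501 with an estimated correlation). Oasl1 rose 4.14-fold to 25.4 ± 7.52 CPM, and Ifit3 3.31-fold to 18.6 ± 6.33. Rtp4 rose 3.13-fold to 277 ± 89.8 and Ifit1 2.25-fold to 50.6 ± 19.7 (adjusted p = 0.0015), while Nmi fell by 0.90 ± 0.16. Isg15 (0.46 ± 0.18, adjusted p = 0.062) and Irf7 (0.41, adjusted p = 0.094) were not called. Isg15 was called without STM3006 library 1 (0.68, adjusted p = 0.0016) and with the length correction (0.61, adjusted p = 0.026). Nucleic acid sensing had 9 of 19 higher, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.5e-04, adjusted p = 0.0447 with an estimated correlation). Tlr3 was 2.29-fold higher at 199 ± 33.3 CPM, and Tmem173 and the signalling adaptor gene Traf3 rose by 1.02 and 0.66 on the log2 scale. NF-kB targets had 10 of 17 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 4.7e-04, adjusted p = 0.0489 with an estimated correlation). The adhesion molecule gene Vcam1 was 6.55-fold higher, Nfkbia, an inhibitor of NF-kB, 2.37-fold and Rela 1.95-fold. Chemokines and cytokines had 5 of 15 higher (camera adjusted p = 0.0138, adjusted p = 0.259 with an estimated correlation). Cxcl16 and Csf1 had log2 changes of 1.09 and 1.03. In MHC class I and antigen processing 2 of 22 were higher and 1 lower (camera adjusted p = 0.366). H2-K1 was higher by 0.40 (adjusted p = 0.017), a call that ended without DMSO library 1 (adjusted p = 0.0752) or STM3006 library 2 (adjusted p = 0.0508) and with only the 6 libraries compared (adjusted p = 0.118). B2m (-0.08) and Tap1 (0.02) were not called.

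The m6A writer complex had 4 of 8 higher and 5 adjusted over the list alone at 48 h of STM3006 (camera adjusted p = 0.0554). Readers and erasers had 4 of 12 higher and 2 lower (0.803). Cbll1, Ythdf2, Ythdf1 and Ythdc1 had log2 changes of 1.03, 1.06, 1.04 and 0.86. DNA replication and G1/S had 14 of 30 lower and 17 adjusted over the list alone (camera adjusted p = 1.2e-04, adjusted p = 0.181 with an estimated correlation). Ccne2, Uhrf1, Pcna and Rrm2 had log2 changes of -0.93, -0.66, -0.62 and -0.57. G2/M and mitosis had 7 of 30 lower and 2 higher (camera adjusted p = 0.0221, adjusted p = 0.147 with an estimated correlation), with Cdca8 at -0.68 and Mki67 at 0.60. Hypoxia and glycolysis had 13 of 27 lower and 2 higher (camera adjusted p = 1.2e-04, adjusted p = 0.0582 with an estimated correlation). Egln3 was 4.97-fold lower at 6.91 ± 1.99 CPM and Ankrd37 had a log2 change of -2.19. The integrated stress response had 11 of 24 lower and 1 higher (camera adjusted p = 0.0117, adjusted p = 0.0545 with an estimated correlation). Vldlr and Atf5 had log2 changes of -1.12 and -1.05 and Atf3 of 1.28. Of the p53 targets 11 of 25 were higher and 4 lower (camera adjusted p = 0.0895), with Gdf15 3.50-fold higher at 63.2 ± 16.8 CPM, Btg2 at 1.17 and Sesn2 at -1.0. Cytosolic ribosomal proteins had 16 of 78 lower and 1 higher (camera adjusted p = 0.00226, adjusted p = 0.501 with an estimated correlation).

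Mesenchymal and matrix genes had 8 of 28 higher and 5 lower at 48 h of STM3006 (camera adjusted p = 0.436), with the fibronectin gene Fn1 2.45-fold higher at 2458 ± 680 CPM and Vim at -1.13. Epithelial genes had 4 of 22 higher and 6 lower (0.445). Krt5 had a log2 change of -1.67. Cholesterol genes had 1 of 23 higher and 4 lower (0.109), with Srebf2, the transcription factor gene of the pathway, at -0.93 and Sqle at -0.55. Members higher and lower were 6 and 4 of 27 immediate early genes, with Fosl2 at 1.39 and Dusp6 at -1.59, and 6 and 7 of 28 for MYC and ribosome biogenesis. They were 5 and 4 of 28 for lysosome and autophagy, 3 and 2 of 17 for the unfolded protein response, 4 and 2 of 22 apoptosis regulators, 3 and 1 of 13 for interferons, receptors and JAK-SOCS signalling, and 3 and 0 of 9 immune checkpoint ligands. They were 1 and 0 leukocyte, 3 and 1 fibroblast, 1 and 1 endothelial and 0 and 0 adipocyte markers, 1 and 1 of 21 mitochondrial-encoded transcripts, and 45 and 13 of 227 zinc finger genes. Camera adjusted p-values of these lists ran from 0.0634 to 0.963. Median, mean and test differed in sign for m6A readers and erasers, apoptosis regulators and epithelial genes. Without STM3006 library 2, chosen after seeing the data as the library to doubt, 2826 genes were called. In that fit 18 interferon-stimulated genes were higher and 5 lower (camera adjusted p = 0.0327, adjusted p = 0.627 with an estimated correlation). The writer complex was called (camera adjusted p = 0.0327, adjusted p = 0.176 with an estimated correlation), replication genes had 9 lower, epithelial genes 3 lower and ribosomal proteins 34 lower and 2 higher. Without it, the nucleic acid sensing and NF-kB calls were lost with an estimated correlation (adjusted p = 0.0633 and adjusted p = 0.0655). With only the 6 libraries compared, 1252 genes were called.

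**Figure D3:**
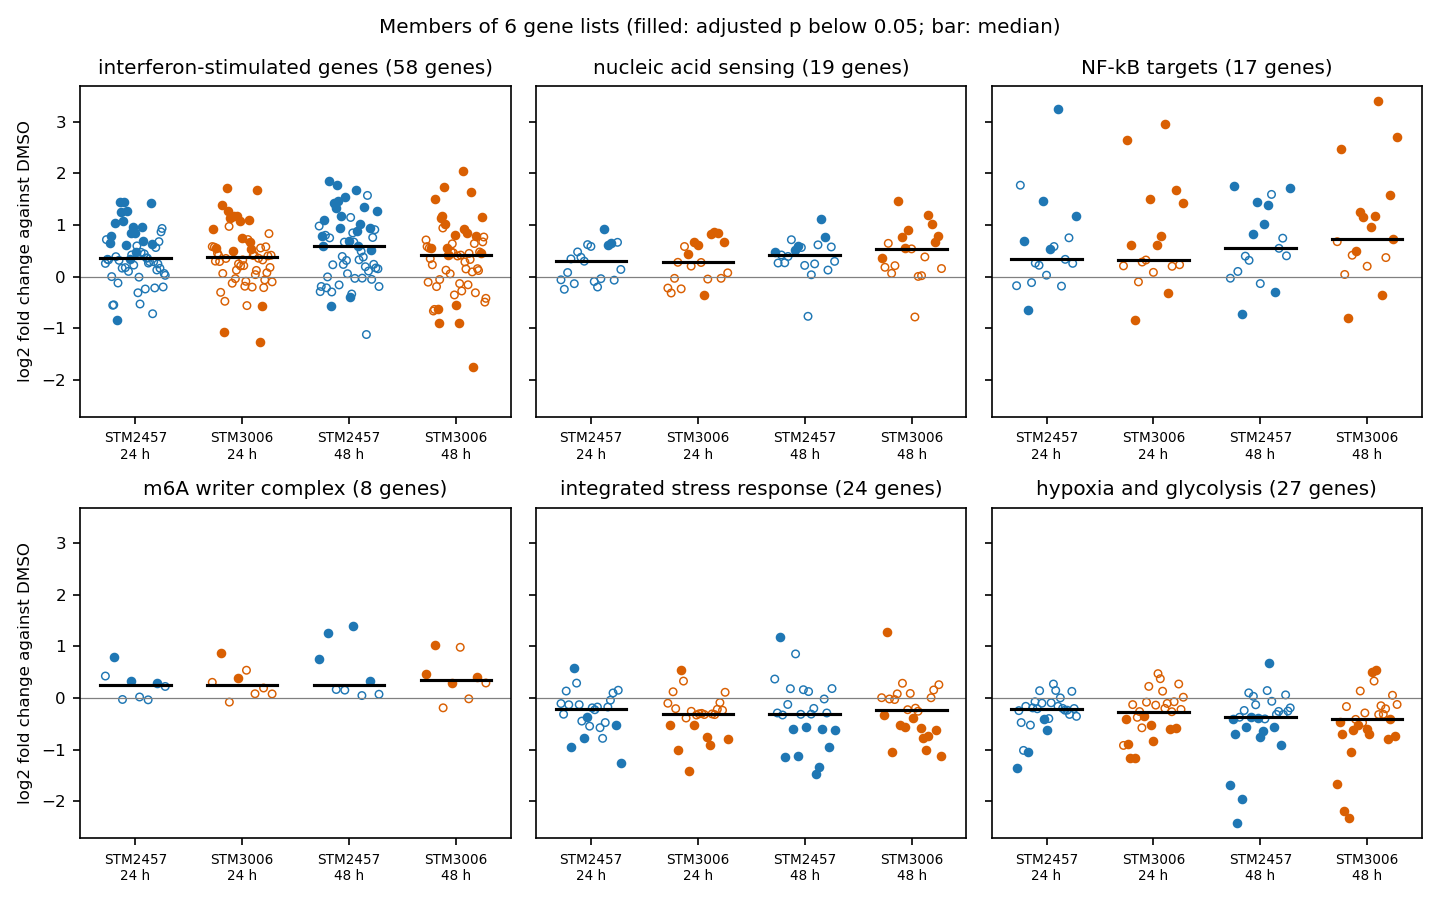
Log2 fold change against DMSO (y axis) of each member of 6 gene lists under STM2457 and STM3006 at 24 h and 48 h, with members of adjusted p below 0.05 filled and the median as a bar. The median of the 58 interferon-stimulated genes was 0.35 and 0.38 at 24 h and 0.59 and 0.41 at 48 h for STM2457 and STM3006.

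The compounds changed many genes in the same direction. At 24 h 742 genes were higher with both compounds and 348 lower with both, against 105 and 39.7 for independent lists, and 1 gene was called in opposite directions. At 48 h 908 were higher with both and 721 lower, against 178 and 137, and again 1 was opposite. Across genes the Pearson correlation of the log2 changes was 0.80 at 24 h and 0.797 at 48 h. Genes are not independent replicates, and the compounds shared the DMSO libraries of their time, which by itself gave correlations of 0.505 and 0.515 in data simulated without any effect. Between comparisons that share no library the correlation was 0.597 for STM2457 at 24 h with STM3006 at 48 h, and 0.548 for the reverse. In the former 590 genes were higher in both and 278 lower, against 135 and 57.3 for independent lists, and 11 were opposite. In the reverse 608 were higher in both and 407 lower, against 139 and 94.9, and 18 were opposite. As covariances, 0.196 and 0.264 were measured at 24 h and 48 h against 0.0407 and 0.0408 simulated. Without a shared library the covariances were 0.163 (STM2457 at 24 h, STM3006 at 48 h) and 0.162 (the reverse). Sharing DMSO libraries cannot account for those values, which compare different times. The 3 DMSO libraries of a time were too few to give each compound 2 of its own, so part of the excess at a matched time may come from sharing them.

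STM3006 was compared with STM2457 at each time to ask where the treatments as given differed, since the doses were not matched. At 24 h 11 genes were called, 4 higher and 7 lower with STM3006. Cyp1b1, an oxidase of steroids and xenobiotics (ENSMUSG00000024087, chromosome 17, 79701537 to 79715061), was lower with STM3006 at 88.1 ± 4.40 against 161 ± 4.97 CPM (log2 change -0.87 ± 0.12, adjusted p = 0.0015). The histone genes Hist1h1c and Hist1h2bc were lower at -1.42 ± 0.19 and -0.84 ± 0.12. Tgm2, a transglutaminase gene (ENSMUSG00000037820, chromosome 2, 158116402 to 158146436), was higher at 153 ± 14.1 against 66.4 ± 6.37 CPM (1.20 ± 0.18, adjusted p = 0.0033), a call at the threshold without STM2457 library 3 (adjusted p = 0.05). Ifit1 (0.02 ± 0.22) and Isg15 (0.12 ± 0.18) were not called between the compounds, which does not show that the compounds act alike. No member of any list was called over all genes at 24 h by edgeR, where 816 genes of all tested had an unadjusted p below 0.05, and 25 were called by DESeq2. Yet the 23 cholesterol genes as a list were lower with STM3006, with 9 lower adjusted over the list alone, a median of -0.30 and 2 members above 0. The list was called (camera adjusted p = 4.5e-12, adjusted p = 3.4e-04 with an estimated correlation). The other camera calls at 24 h were lost with an estimated correlation, namely replication genes lower (camera adjusted p = 0.0304, adjusted p = 0.609 with an estimated correlation) and p53 targets higher (0.0246, adjusted p = 0.355). So were mesenchymal and matrix genes higher (0.0147, adjusted p = 0.0795) and ribosomal proteins lower (0.0183, adjusted p = 0.609). For the remaining 24 lists camera adjusted p-values ran from 0.0621 to 0.927, with median, mean and test of differing sign for nucleic acid sensing and MHC class I. The 11 genes became 6, 7 and 3 without STM2457 library 1, 2 and 3, 5 without STM3006 library 3, and 31 with only the 6 libraries compared in the fit, where the balance turned round (18 higher, 13 lower).

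At 48 h 80 genes were called between the compounds, 56 higher and 24 lower with STM3006. Tgm2 was 3.38-fold higher at 249 ± 84.8 against 73.7 ± 8.02 CPM (1.76 ± 0.18, adjusted p = 1.8e-05), and Cyp1b1 2.79-fold lower at 67.9 ± 12.4 against 189 ± 3.66 (-1.48 ± 0.12, adjusted p = 2.8e-07). Cyp26b1 was higher at 52.8 ± 9.26 against 19.3 ± 3.04 CPM (adjusted p = 2.8e-04). Aldh3a1, an aldehyde dehydrogenase gene, was lower at 2.04 ± 0.296 against 8.06 ± 0.468 (adjusted p = 0.0014). Both calls ended with only the 6 libraries compared (adjusted p = 0.0548 and adjusted p = 0.0997). The interferon-stimulated genes were lower as a list with STM3006, with 1 of 58 called lower over all genes and adjusted over the list alone, a median of -0.25 and 14 members above 0. The list was called (camera adjusted p = 3.2e-04, adjusted p = 0.459 with an estimated correlation). The called member was Iigp1, at 34.8 ± 1.83 against 59.1 ± 2.99 CPM (adjusted p = 0.0081), a call that ended without STM2457 library 2 (adjusted p = 0.0553) or 3 (adjusted p = 0.0601) and with only the 6 libraries compared (adjusted p = 0.296). Ifit1 (-0.24 ± 0.22) and Isg15 (0.15 ± 0.18) were not called. The cholesterol genes were again lower as a list, with none called over all genes, 2 lower adjusted over the list alone and a median of -0.17. The list was called (camera adjusted p = 3.2e-04, adjusted p = 0.0404 with an estimated correlation). The other 27 lists had no call, with camera adjusted p-values of 0.0725 to 0.922 and differing signs of median, mean and test for nucleic acid sensing, the unfolded protein response and epithelial genes. The lysosome list was called without STM3006 library 2 (camera adjusted p = 0.019, adjusted p = 0.402 with an estimated correlation). The 80 genes became 13, 17 (8 higher, 9 lower) and 25 without STM2457 library 1, 2 and 3, and 880, 32 and 777 without STM3006 library 1, 2 and 3. They became 3 (1 higher, 2 lower) with only the 6 libraries compared, 38 with the replicate number as a block and 157 by DESeq2.

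**Figure D4:**
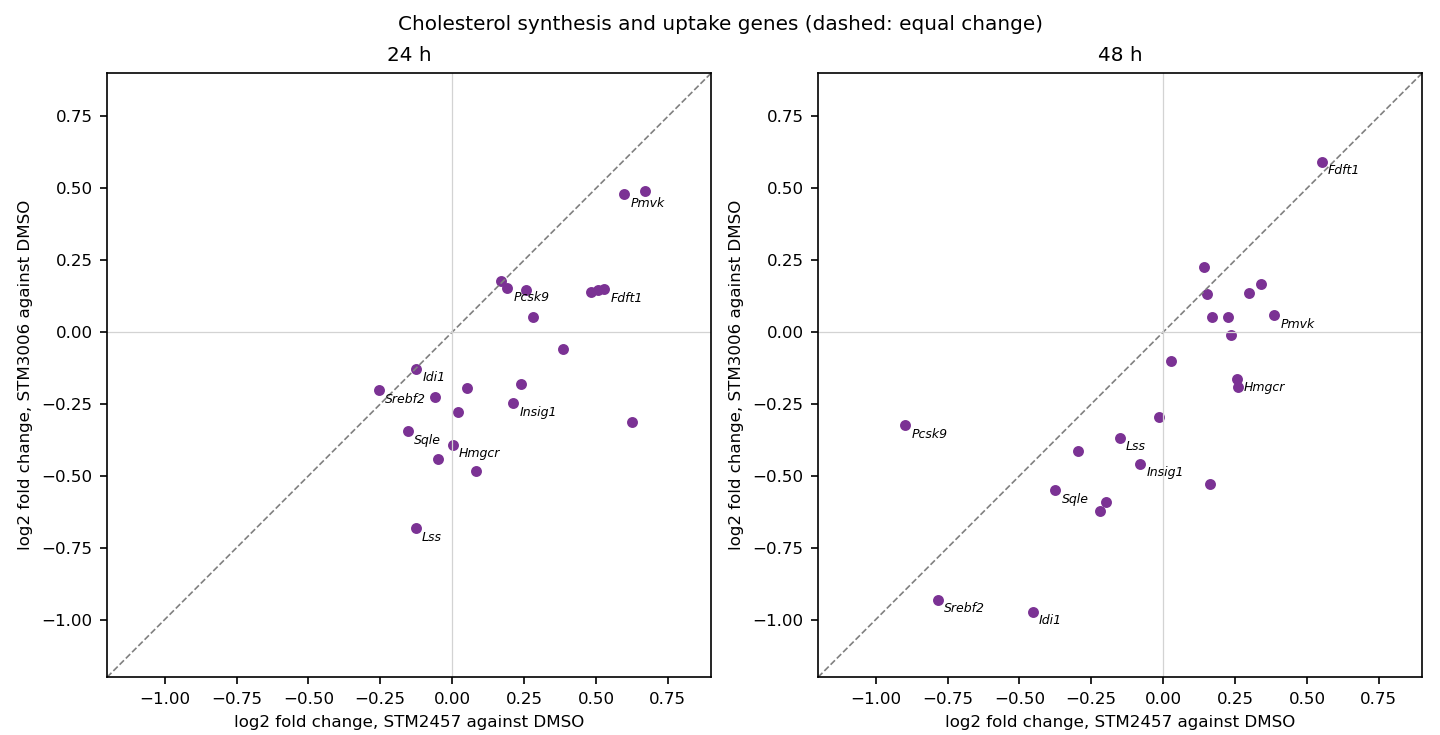
Log2 fold change against DMSO of the 23 genes of cholesterol synthesis and uptake under STM2457 (x axis) and STM3006 (y axis) at 24 h and 48 h, with each point a gene and the dashed line marking equal change. The median change at 24 h was 0.19 with STM2457 and -0.18 with STM3006.

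DMSO cultures at 48 h were compared with those at 24 h to show what time in culture did without a compound. Il1rn fell 6.28-fold from 9.20 ± 0.625 to 1.43 ± 0.227 CPM (log2 change -2.65 ± 0.32, adjusted p = 3.3e-05), Aldh3a1 4.85-fold and the transcription factor gene Ovol1 4.82-fold. Ankrd37 rose 3.25-fold from 8.65 ± 2.34 to 28.1 ± 1.54. In total 864 genes were called, 387 higher and 477 lower, and 167 changed at least 2-fold. With the GC correction 675 were called, 529 of the 864 among them, and the log2 changes had a Spearman correlation of -0.310 with the GC content of the 3′ end. Interferon-stimulated genes fell with time, 14 of 58 lower and 16 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 3.2e-10, adjusted p = 0.0468 with an estimated correlation). Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481) was 2.25-fold lower, 25.3 ± 5.76 against 57.0 ± 9.67 CPM (adjusted p = 5.3e-04), and Ifit3 2.87-fold lower. Isg15 was called lower at -0.75 (adjusted p = 0.018), not without DMSO 24 h library 1 (0.0517) or 3 (0.061), DMSO 48 h library 3 (0.108) or with the GC correction (0.0686). MHC class I and antigen processing had 4 of 22 lower (camera adjusted p = 0.0925), with Tap1, the peptide transporter gene, at -0.68 (adjusted p = 0.0027). Nucleic acid sensing had 3 of 19 lower (0.0549). Chemokines and cytokines had 2 of 15 lower (camera adjusted p = 0.0426, adjusted p = 0.308 with an estimated correlation), with Cxcl5 2.10-fold lower.

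With time in DMSO cholesterol genes had 9 of 23 higher and 14 adjusted over the list alone (camera adjusted p = 2.4e-10, adjusted p = 6.4e-04 with an estimated correlation), with Insig1 and Cyp51 1.87-fold and 1.61-fold higher. The integrated stress response had 7 of 24 higher (camera adjusted p = 1e-06, adjusted p = 0.00124 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, 2.31-fold and Ddit4 1.92-fold higher. Hypoxia and glycolysis had 9 of 27 higher (camera adjusted p = 4.4e-07, adjusted p = 0.0249 with an estimated correlation). Pdk1 had a log2 change of 0.73. The unfolded protein response had 5 of 17 higher (camera adjusted p = 1.1e-05, adjusted p = 0.0337 with an estimated correlation). Xbp1 had a log2 change of 0.85 ± 0.13. Mitochondrial-encoded transcripts had 8 of 21 lower and 12 adjusted over the list alone (camera adjusted p = 4.4e-10, adjusted p = 0.0337 with an estimated correlation), and their share of counts was 3.01 ± 0.266% at 24 h and 2.10 ± 0.227% at 48 h. With an estimated correlation the other camera calls were lost, namely G2/M and mitosis 4 of 30 higher and 2 lower (camera adjusted p = 0.00992, adjusted p = 0.0688), MYC and ribosome biogenesis 3 of 28 lower (0.00404, adjusted p = 0.308) and epithelial genes 1 of 22 higher and 5 lower (0.0438, adjusted p = 0.142). So were those of immediate early genes, 1 of 27 higher and 4 lower (0.0426, adjusted p = 0.384), ribosomal proteins 2 of 78 lower (0.00404, adjusted p = 0.466) and both leukocyte markers lower (0.00959, adjusted p = 0.0709). The epithelial list had a median of 0.02 and a mean of -0.14, so its median and test differed in sign. The remaining 16 lists were not called, with camera adjusted p-values of 0.0549 to 0.983. Median, mean and test differed in sign for JAK-SOCS signalling, p53 targets, apoptosis regulators, fibroblast markers and zinc finger genes. The 864 genes became 293 (76 higher, 217 lower), 394 (131, 263) and 341 (69, 272) without DMSO 24 h library 1, 2 and 3. They became 405 (140, 265) and 249 (84, 165) without DMSO 48 h library 2 and 3, and 2258 (1139, 1119) with only the 6 libraries compared. The 14 interferon-stimulated genes became 8, 9, 6 and 5 without DMSO 24 h library 1, 2 and 3 and DMSO 48 h library 3.

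The change of each compound's effect from 24 h to 48 h was tested directly. With STM2457 13 genes were called, 8 higher and 5 lower, a balance that turned round in some alternatives given below. Il1rn went from 0.96 at 24 h to 3.30 at 48 h, a difference of 2.34 ± 0.39 (adjusted p = 0.0078), Cyp1b1 from 0.44 to 1.82 (adjusted p = 4.5e-04), Cxcl5 from 0.15 to 1.41 (adjusted p = 0.0018) and Epas1, a hypoxia-inducible transcription factor gene, from 0.40 to 1.54 (adjusted p = 0.0075). H19 went from -1.33 to -3.39 (adjusted p = 0.0026). In the DMSO cultures Il1rn and Cxcl5 fell over the same interval, by 2.65 and 1.07. The cytosolic ribosomal proteins were the one list called, with a median difference of -0.29 and none of 78 called over all genes (camera adjusted p = 3.9e-06, adjusted p = 0.608 with an estimated correlation). The 13 genes became 8 and 7 without DMSO 24 h library 2 and 3, 7 without STM2457 24 h library 1, 8 and 43 without DMSO 48 h library 1 and 3 (11 higher and 32 lower in the latter), and 8 without STM2457 48 h library 1. They became 20 with a mean of at least 5 CPM (8 higher, 12 lower), 60 by DESeq2 (25 and 35) and 326 with only the 12 libraries compared (113 and 213).

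With STM3006 67 genes were called, 51 higher and 16 lower. Il1rn went from 0.62 to 2.95, a difference of 2.33 ± 0.39 (adjusted p = 0.0067), Rnf213, which encodes a large ubiquitin ligase, from -0.42 to 1.15 (1.56 ± 0.26, adjusted p = 0.0067), and Utrn, the dystrophin relative utrophin, from -1.22 to 0.55 (1.77 ± 0.31, adjusted p = 0.009). Cxcl5 went from 0.17 to 1.61 (adjusted p = 3.6e-04). In the DMSO cultures Il1rn, Rnf213, Utrn and Cxcl5 changed by -2.65, -0.70, -0.65 and -1.07 over the same interval, which the difference subtracts. The effects on Isg15 (-0.62 ± 0.25, adjusted p = 0.28) and Oasl1 (0.96 ± 0.31, adjusted p = 0.16) were not shown to differ between the times. No list was called by camera, with adjusted p-values of 0.11 to 0.999, though the ribosomal proteins were called without STM3006 48 h library 2 (camera adjusted p = 5.2e-05, adjusted p = 0.758 with an estimated correlation). The 67 genes became 21 and 22 without DMSO 24 h library 2 and 3, 29 and 31 without STM3006 24 h library 2 and 3, 25 and 32 without DMSO 48 h library 1 and 2, and 203, 182 and 245 without STM3006 48 h library 1, 2 and 3. They became 34 with the replicate number as a block, 155 by DESeq2 and 18 with only the 12 libraries compared.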

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

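The tests of GC content, length, single libraries, culture age and dose below, and the splits that exchange as many libraries at both times, were chosen only after the results were seen. The other splits were planned.

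The effect of STM2457 differed between 48 h and 24 h, by the test of the difference, for 13 genes. Among them the differences (log2) were 2.34 for Il1rn, 1.38 for Cyp1b1, 1.26 for Cxcl5 and 1.14 for Epas1, and -2.06 for H19, -1.32 for Col18a1, -1.10 for Igfbp2 and -1.02 for Dusp6. The call was lost without single libraries for Dusp6 (without DMSO 24 h library 3, -0.94, adjusted p = 0.0542), for Col18a1 (without any of 5 libraries, adjusted p up to 0.085) and for Igfbp2 (without any of 10 libraries, adjusted p up to 0.143, and with the GC correction, -1.03, or the length correction, -1.04). The list of cytosolic ribosomal proteins differed as well (camera adjusted p = 3.9e-06, adjusted p = 0.608 with an estimated correlation). Of the 40 planned splits of the 12 libraries 8 called as many genes as the real split, up to 3231, so chance is not excluded. That many calls point to the structure of the splits, which carry the compound's own effect at one time into the difference. Of the 40 splits that exchange as many libraries at both times 1 called as many, the real one, and the highest other called 0. Those splits mix treated and DMSO libraries in every group, which widens the spread within groups, so their few calls exclude nothing.

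The effect of STM3006 differed between 48 h and 24 h for 67 genes. Among them the differences were 2.33 for Il1rn, 1.77 for Utrn, 1.56 for Rnf213 and 1.53 for Bmp2, and -1.81 for Bcl11b, -1.67 for Ckb, -1.47 for Tfap4 and -1.43 for H19. Il1rn, Utrn and Rnf213 kept their call without each library in turn, whereas the call was lost without DMSO 24 h library 2 or DMSO 48 h library 1 for Bmp2 (adjusted p = 0.0979 and adjusted p = 0.0921), Ckb (0.0631 and 0.0706), H19 (0.0896 and 0.0584), Tfap4 (0.126 and 0.0983) and Bcl11b (0.124 and 0.123). It was also lost without STM3006 24 h library 2 for Bmp2 (0.0534), H19 (0.0837), Tfap4 (0.111) and Bcl11b (0.0811), and for all but Ckb without further libraries. Of the 40 planned splits 4 called as many genes, up to 913, again with the compound's own effect carried into the difference, so chance is not excluded. Of the 40 that exchange as many at both times 1 called as many, with 15 as the highest other, which excludes nothing for the same reason.

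For these 67 genes 3 technical explanations were weighed. With the GC correction 64 of the 67 were still called, which argues against GC content as the whole cause. Without the STM3006 48 h library with the most counts 66 were still called. Leaving out STM3006 48 h library 1, 2 or 3 raised the total to 203, 182 and 245 genes, so a loss was unlikely from the start. Without DMSO 24 h library 2 or 3 only 21 and 22 of the 67 were still called, though fewer libraries also weaken the test. Dependence on a single library therefore stays open. With the length correction 44 were still called, and the median transcript length was 6151.5 bases among the 50 of the 51 genes called higher that had a length, 2264 among the 16 called lower and 3140 among the 11113 tested genes that had one. Length may therefore account for part of the pattern and stays open. The difference also subtracts the log2 change of DMSO from 24 h to 48 h. That change was -2.65 for Il1rn, -0.65 for Utrn, -0.70 for Rnf213 and -0.71 for Bmp2. It was 0.43 for Bcl11b, 0.022 for Ckb, 0.038 for Tfap4 and 0.96 for H19. Part of a difference may therefore lie in the DMSO cultures, which was not tested. A change of the compound's effect with time, which the design names, also stays open.

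Of the 58 interferon-stimulated genes 16 to 21 were called higher and 1 to 5 lower in the 4 comparisons of a compound with DMSO, and 14 lower with time in DMSO, so treated cultures that lag the DMSO cultures in age could look the same. The camera calls of the list with the compounds were lost with an estimated correlation (adjusted p = 0.145 and 0.336 at 24 h, 0.0937 and 0.501 at 48 h). Fry called the list higher with STM2457 at 24 h and 48 h (adjusted p = 0.00254 and 4.1e-04) and with STM3006 at 24 h (adjusted p = 0.00377). For STM3006 at 48 h without library 2, fry's adjusted p was 0.0513. Fry does not compare the list with other genes. No DMSO culture younger than 24 h was measured, so a lag at 24 h could not be tested. The mitochondrial-encoded transcripts, with a median change of -0.515 with time, argue against a lag as the whole cause at 48 h. They had an upper quartile of log2 changes of 0.0879 with STM2457 and 0.182 with STM3006. The bound set for a lag, chosen after the results were seen, was a median of 0.257, which is 1/2 of their fall. A shorter lag is not covered by it. The mitochondrial-encoded share of counts did go part of the way back, from 2.10% in DMSO at 48 h to 2.31% with STM2457 and 2.47% with STM3006, against 3.01% in DMSO at 24 h. Of the 13 lists called with time, 8 moved back by at least 1/2 with STM2457 at 48 h and 7 with STM3006. But the DMSO libraries of 48 h enter both comparisons with opposite signs, which by itself favours such a return, so this decides nothing for or against a lag. GC content and a single library are argued against as well, since 21 interferon-stimulated genes were called higher at 48 h of STM2457 with the GC correction and at least 11 in each of the 4 comparisons without any library. An effect of the treatment, which the design names, remains a hypothesis. A lag stays open at 24 h, and in part of the response at 48 h.

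The cholesterol genes were lower with STM3006 than with STM2457. A stronger effect of the same kind would move the list the same way with both compounds. The median log2 change at 24 h was 0.190 with STM2457 and -0.179 with STM3006, but the quartiles lay on both sides of 0 (-0.0237 to 0.434 and -0.295 to 0.148). Camera called the list against DMSO with neither compound (adjusted p = 0.0502 and 0.242, 0.145 and 0.387 with an estimated correlation), while fry called it higher with STM2457 (adjusted p = 9.4e-04) and lower with STM3006 (adjusted p = 0.0343). Fry's opposite calls argue against a stronger effect of the same kind for the list at 24 h, though fry does not compare it with other genes. At 48 h fry did not call the list with STM2457 (adjusted p = 0.358), so such an effect stays open there. The list was still called at 24 h with the GC correction (camera adjusted p = 4.5e-10), and without any of the 6 libraries in turn the camera adjusted p was at most 1.6e-09. The dose, 20 µM against 2 µM, differs with the compound and may matter as much, so these values do not separate compound from dose.

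For the 7 comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The real split called 1302, 2367, 2188 and 3192 genes for the compounds against DMSO (STM2457 and STM3006 at 24 h, then at 48 h), 11 and 80 between the compounds and 864 between the DMSO times, and in each case 1 of the 10 splits called as many, the real one. The highest of the other splits called 2, 0, 0 and 38, then 0 and 0, and 0. All other splits mix libraries of the groups compared, which widens the spread within groups, so their few calls exclude nothing.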

How the results depend on the processing

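The corrections for GC content and transcript length and the lists without STM3006 48 h library 2 were chosen after seeing the data, the other alternatives before. Of 584 results for named genes, 548 of them called, 354 kept direction and side of the threshold under every alternative and every library left out, and 33 values reversed, all of genes that were not called. The share of called genes that were higher moved by less than 10 points between TMM and DESeq2's size factors. The shift of a gene's log2 change between them had a median over genes of at most 0.0225 in size. The cause of the changes below was not tested. Leaving out a library leaves fewer, and a fit of only the libraries compared estimates the spread from those alone. Such a fit called fewer genes in each comparison with STM3006 at 48 h and more in all others. The number of libraries alone does not account for that. The STM3006 48 h libraries spread most, with residual SDs of 0.298, 0.387 and 0.329 against 0.194 to 0.287 elsewhere. Main counts may therefore be too high where those libraries enter and too low in the other comparisons. Mettl3 (0 to 5 counts) and Cxcl10 (1 to 16) had too few counts to test, and the cause of that was not tested.

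Genes called with only the libraries compared were 2129 and 3603 (STM2457 and STM3006 against DMSO, 24 h), 3342 and 1252 (48 h), 31 and 3 (STM3006 against STM2457, 24 h and 48 h), 2258 (DMSO, 48 h against 24 h), and 326 and 18 (difference of the STM2457 and STM3006 effects). DESeq2 called 25 and 157 (STM3006 against STM2457, 24 h and 48 h) and 60 and 155 (differences of effects). The replicate number as a block gave 38 (STM3006 against STM2457, 48 h) and 34 (difference of STM3006 effects). Libraries of the same number mostly did not pair, with 2 of 18 correlations above 0.1 and a range of -0.227 to 0.299. Both were between STM2457 and STM3006 at 24 h, 0.211 for number 2 and 0.299 for number 3. A pairing there is not excluded, and the block called 10 genes there, 7 of the 11 main ones among them. Different numbers reached 0.312 (STM2457 library 1 with STM3006 library 3 at 48 h). A filter at a mean of 5 CPM gave 20 (difference of STM2457 effects). The camera call of the interferon-stimulated genes was lost with an estimated correlation, with adjusted p = 0.145 and 0.336 at 24 h and 0.0937 and 0.501 at 48 h. Fry called the list with STM2457 at both times and with STM3006 at 24 h. Over all lists camera with the preset correlation made 54 calls in 9 comparisons, of which 37 were lost with an estimated correlation and 10 with fry, while fry made 35 others.

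Leaving out each library in turn gave 730 to 1048 and 1483 to 1794 genes (STM2457 and STM3006, 24 h), 1370 to 1932 and 2335 to 3581 (48 h), 3 to 9 and 13 to 880 (STM3006 against STM2457, 24 h and 48 h), 249 to 678 (DMSO), and 7 to 43 and 21 to 245 (differences of effects). Interferon-stimulated genes higher were 11 to 16 and 13 to 17 at 24 h and 17 to 19 and 13 to 19 at 48 h, and 5 to 13 lower with time in DMSO. Those lower with STM2457 and STM3006 were 1 and 1 to 3 at 24 h, and 1 to 2 and 5 to 8 at 48 h.

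Log2 changes that reversed without a library, as the range over libraries, were -0.0195 to 0.21 (Irf7), -0.17 to 0.19 (Mettl14) and -0.0456 to 0.17 (B2m) for STM2457 at 24 h, -0.0060 to 0.23 (H2-K1) and -0.16 to 0.0879 (Irf7) for STM3006 at 24 h, -0.20 to 0.16 (B2m) for STM2457 at 48 h, and -0.0505 to 0.14 (Tap1) and -0.26 to 0.11 (B2m) for STM3006 at 48 h. Between STM3006 and STM2457 they were -0.26 to 0.0738 (Mettl14), -0.0953 to 0.15 (Ifit1), -0.0022 to 0.24 (Isg15) and -0.0468 to 0.11 (B2m) at 24 h, and -0.18 to 0.12 (Irf7), -0.11 to 0.0021 (B2m), -0.0210 to 0.37 (Isg15) and -0.0468 to 0.10 (H2-K1) at 48 h. B2m reversed with the length correction at 48 h (0.0791 with STM2457, 0.0663 with STM3006), Tap1 with the GC correction (STM3006, 48 h, -0.00895), and Irf7 (STM3006 against STM2457, 48 h) with the block (-0.00458) and the GC correction (-0.00371).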

Other observations

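Further members of the lists changed. With STM3006 at 48 h the zinc finger genes Zfp579, Zfp750 and Zfp513 were higher by 1.61, 1.53 and 0.96 (log2), and Zfp750, a regulator of epidermal differentiation, was higher with STM2457 by 1.48 at 24 h and 1.69 at 48 h. Socs3, an inhibitor of JAK signalling, was lower at 48 h with both compounds (-0.72 and -0.80). The collagen genes Col1a1 and Col6a1 were lower with STM2457 at 48 h (-1.57 and -0.98).

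The correlations with exons below were planned, while the bound set for them and the regression with length were chosen only after the results were seen. Methylation of adenosine is enriched in long internal exons, so transcripts with longer internal exons could change more when METTL3 is inhibited. Across 10105 genes the Spearman correlation of the log2 change with the longest internal exon was 0.0808 and 0.142 for STM2457 and STM3006 at 24 h and 0.122 and 0.170 at 48 h. In DMSO at 48 h against 24 h it was -0.112, so 3 of the 4 values exceed the size of that background and the lowest, 0.0808, does not. With expression and transcript length as further predictors in a rank regression the slopes were 0.107 and 0.118 at 24 h and 0.0846 and 0.1104 at 48 h, against -0.1095 in DMSO, so 2 of the 4 exceed that size, 1 of them barely. Transcript length itself had correlations of -0.00592 and 0.0747 at 24 h and 0.110 and 0.16 at 48 h, against -0.0320 in DMSO. The GC content of the 3′ end had a correlation of -0.310 in DMSO and of -0.0519 to 0.0258 with the compounds, so the background carries a GC trend. Each compound was compared with DMSO of its own time, where a trend with time common to treated and DMSO cultures cancels. These values therefore do not show whether the treated cultures carry that trend. With the number of exons the correlations were -0.191 and -0.166 at 24 h and -0.0532 and -0.0444 at 48 h, against -0.0510 in DMSO. Genes are not independent replicates, and the question stays open.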
